A study of Oryza sativa with 6 samples.

How the data were processed

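Total RNA was extracted with Trizol from 4-5 mm inflorescences of sro and wild type rice (Japonica variety 9522), 3 biological replicates each, and 500 ng per sample was turned into biotinylated cRNA and hybridised to Affymetrix rice arrays, per the labels. The deposited values are 1 column per array of log2 intensities per probe set. RMA and Partek are named in the submitters' processing notes, without versions, roles or order. RMA corrects background, normalizes arrays to one another and summarises the probes of a set. That the scale is log2 was inferred from the values, which run from about 2 to about 14 with nearly equal medians. The RMA settings, detection calls and scan dates are not given in the sources used here. The scanner files were not used here, and the number of arrays limits precision. With no detection calls, the mean of the 10 Magnaporthe control probe sets of each array (probe set means between 3.66 and 5.88) served as a level without target, a choice made after the values were seen. Where a gene's dimmer group averaged below it, the fold is a lower limit, the brighter group's mean against the mean of, per array, the higher of the gene's value and that level.

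The values were used as deposited, with no further normalization, floor or filter, except that 123 of the 57381 probe sets, Affymetrix controls whose names begin with AFFX, were left out of the tests. The 64 reporter control probe sets stayed in, and 1 of them was called. Probe sets were paired with genes through the GEO platform annotation. There 22436 probe sets had 1 gene, 95 had several and were not named, and 34727 of those tested had none listed. All 17905 genes were matched by gene number to RefSeq genes of the assembly ASM3414082v1, which gave a name other than a locus number for 2457 genes. Coordinates are not printed, since the array's build is not stated, and the assembly was used for names, chromosomes and gene order only.

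The comparison of sro with wild type used limma 3.58.1 in R 4.3.3, with lmFit and eBayes without trend on each probe set, no covariates, two-sided tests and Benjamini-Hochberg adjustment over the 57258 probe sets. Adjusted p under 0.05 was the threshold for a call. Each p of a gene in the text is this limma adjusted p unless another test is named. The median standard error of a log2 change was 0.08. Gene lists were tested on 1 probe set per gene, the one with the highest mean over the 6 arrays, with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, each adjusted over the lists. Members were also counted with p adjusted over the list alone. Single control values were compared with two-sided exact permutation tests, whose smallest p with 3 against 3 arrays is 0.1. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for gene names and figures.

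The lists cover floral organ identity, meristem and inflorescence regulators, anther, tapetum and early germ cells, pollen and late anther, auxin, cytokinin, gibberellin, brassinosteroid, jasmonate, ethylene, abscisic acid, cyclins and CDK regulators, DNA replication, histones, YABBY, WOX and KNOX genes, growth-regulating factors with TCP and SPL genes, C2H2 zinc fingers, cell wall expansion, cellulose and pectin, lipid transfer and cutin, photosynthesis, ribosomal proteins, heat shock, defence, seed storage, cytochrome P450 and the circadian clock. There were 27 lists, of which 26 had at least 4 measured genes and were tested. The comparison, its test, the lists, the rule for naming genes and the other settings to be tried were fixed before the data were examined. The lists had been written as gene descriptions and rice annotation numbers. Since the tables hold symbols only, they were translated into symbol patterns after the gene tables and array summaries were seen and before any gene's change was seen. A list therefore holds only genes with a matching symbol, and some genes stand in more than 1 list. Some patterns also took in genes outside the written descriptions, such as FEN1A, FEN1B and OsRFC1 to OsRFC5 among the DNA replication genes. Of these, OsRFC3 and OsRFC5 were called lower. Others were Roc genes (lipid transfer and cutin), OsTIP3;1 and OsTIP3;2 (seed storage), and CHLD and PORA (photosynthesis). An exploratory comparison was run before the methods were tested on simulated data.

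The genes named are the 12 with the largest rise and the 12 with the largest fall among called probe sets with 1 named gene whose 2 groups did not overlap (in place of descriptions, which the tables lack, a name other than a locus number was required), taking the probe set with the smallest p per gene. To these come all called floral organ identity genes, OsMADS3, OsMADS13, OsMADS16, OsMADS58 and DL whether called or not, and up to 4 members of every other list with the smallest p. A further few members of lists (JAZ3, JAZ4 and LOX1.1) were chosen after their values were seen. Display names were chosen among a gene's aliases, in part after the values were seen, with no effect on which genes were selected.

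The tests were run on simulated data before the results were drawn. These used each probe set's mean over the real arrays and its spread as estimated by eBayes. Of the 67 probe sets changed by a log2 of 0.5, 77.6% were recovered, as were 98.5% of 67 changed by 1 and all 66 changed by 2. Of 198 calls, 14 (7.07%) were probe sets left unchanged. A list shifted by 0.3 was called, and 0 of the 25 other lists were. The simulated noise was independent between probe sets, whereas the real DNA replication list had an estimated correlation of 0.60. Its spread was the one the tested model assumes, equal in both groups. Real genes can differ from that, as MCM7 did (SD 0.90 in wild type and 0.16 in sro). Far fewer probe sets were changed than the 8377 called in the data. These rates and the list result therefore need not carry over to the real arrays.

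Alternatives were the replicate number as a block, renewed quantile normalization, centring of each array on its median, only probe sets at or above the median level, values floored at the 20th percentile of each array, an intensity trend, robust eBayes, an unmoderated linear model, array weights, 1 probe set per gene or the mean of all, at least 2-fold change, an estimated correlation, and each array left out in turn. Added after seeing the data were fits with sro replicate 2 as the only sro array, chosen because its dap spike lay nearest to wild type, and fits without the genes of chromosome 1. Gene positions were shuffled 10000 times to ask how many strongly changed genes fall on one chromosome by chance. All 10 splits of the 6 arrays into groups of 3 were fitted.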

Results

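In young inflorescences of the rice sro mutant, JAZ13, a repressor of jasmonate responses, rose at least 25.6-fold over wild type (log2 values of 4.52 ± 0.04 in wild type and 9.33 ± 0.05 in sro; SD, n = 3 arrays per group), and OsC6, a lipid transfer protein of the anther tapetum, rose at least 19.4-fold (4.61 ± 0.31 and 9.04 ± 0.18). The ethylene receptor gene ETR2 fell at least 49.2-fold (10.33 ± 0.09 and 4.51 ± 0.27). The replicative helicase genes MCM7 and MCM4 fell by 1.76 (SE 0.38) and 1.60 (SE 0.33) on the log2 scale, and 15 of 30 measured DNA replication genes fell (camera adjusted p = 0.037, and adjusted p = 0.805 with an estimated correlation). Of 21 measured floral organ identity genes, 5, all MADS-box genes, rose by small amounts and 16 did not pass the test. A fold is given as a lower limit where the dimmer group averaged below the probe sets for the fungus Magnaporthe, whose mean was 4.65 in wild type and 4.69 in sro.

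The data are 6 Affymetrix rice arrays, 3 from sro and 3 from wild type of the Japonica variety 9522, each from separately collected 4-5 mm inflorescences grown in the paddy field. At this length SRO reaches its highest expression and most spikelets have begun to form stamens and carpels, per the labels. The comparison asks which transcripts differ between sro and wild type at that time, and cannot by itself assign a difference to SRO. The targeted gene itself was not checked, because no table used here names it. Array medians lay between 5.26 and 5.31 on the log2 scale. Arrays of one genotype correlated at 0.997 to 0.998, and arrays of different genotypes at 0.992 to 0.994, over all probe sets tested. The first principal component held 65.4% of the variance and separated the genotypes, and the second held 12.3% and separated wild type replicates 1 and 2. The number of arrays limits the precision of every value.

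Of the 57258 probe sets tested, 8377 (14.6%) changed at an adjusted p under 0.05, with 3202 higher and 5175 lower in sro. They name 5153 genes. In a refit with 1 probe set per gene, adjusted over these alone, 6809 of 17905 genes were called, 2005 higher and 4804 lower. Of the 6809, 4768 were also called over all 57258 probe sets, the adjustment used for list members below. Falls thus outnumbered rises over all genes, and a list with more falls than rises does not by that stand apart. Most changes were small, with a median absolute log2 change of 0.40 among the called probe sets, and 502 changed at least 2-fold, of which 181 rose and 321 fell. At least 4-fold changes were found for 95 probe sets, 59 higher and 36 lower. In 19791 probe sets (34.6%) the values of the 2 groups did not overlap, where chance gives 10%. The count of called probe sets was 5253 without wild type replicate 3, 5030 without sro replicate 1, 4589 without sro replicate 3 and 4965 in an unmoderated linear model. With sro represented by replicate 2 alone, a comparison chosen after seeing the data, it was 668.

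Labelling controls differed between the groups. The dap spike, measured at its 5 prime end, averaged 7.63 ± 0.12 (SD, n = 3) on the log2 scale in wild type and 9.25 ± 1.20 in sro (two-sided exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Its values were 10.3 in sro replicate 1, 7.95 in replicate 2 and 9.48 in replicate 3. The spike's 3 prime minus 5 prime difference was 4.26 ± 0.08 in wild type and 2.82 ± 1.25 in sro (exact permutation p = 0.1). In sro replicates 1, 2 and 3 that difference was 1.70, 4.17 and 2.58. The 3 prime minus 5 prime difference of actin was 5.18 ± 0.05 in wild type and 4.77 ± 0.27 in sro (exact permutation p = 0.1), and that of GAPDH was 1.65 ± 0.01 and 1.43 ± 0.18 (exact permutation p = 0.1). For cyclophilin it was 0.69 ± 0.06 and 0.60 ± 0.07 (exact permutation p = 0.3).

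Among genes with a name other than a locus number, the repressor genes JAZ13, JAZ9 and JAZ10 were among the 12 largest rises. Some genes with only a locus number rose more, such as LOC4326388 on chromosome 1 (log2 change 5.87). JAZ13 (LOC4348531) had an adjusted p of 1.62e-08, JAZ9 (LOC4331832) rose at least 4.66-fold (from 4.41 ± 0.29 to 6.88 ± 0.18, adjusted p = 7.62e-05), and JAZ10 (LOC4331834) rose 5.20-fold (log2 change 2.38, SE 0.07, adjusted p = 1.01e-06). BHLH148 (LOC4334060), a basic helix-loop-helix transcription factor, rose 4.64-fold. DREB1B (LOC4347618), a regulator of cold and drought responses, rose 9.41-fold (log2 change 3.23, SE 0.33), although its wild-type arrays were widely spread (8.01 ± 0.79 against 11.25 ± 0.14 in sro). The calmodulin-like genes CML15 (LOC4338633) and CML31 (LOC4325408) rose 9.35-fold and 4.61-fold, and OsWRKY71 (LOC4328512), a WRKY transcription factor, rose 4.50-fold. That is a log2 change of 2.17, and a second, dimmer OsWRKY71 probe set rose by only 0.81 (adjusted p = 0.00207). BURP16 (LOC4348595) rose 6.02-fold and the aquaporin gene NIP4-1 (LOC4326119) at least 3.93-fold (from 4.19 ± 0.72 to 6.65 ± 0.07). The jasmonate list as a whole went both ways. Of its 37 measured genes, 6 rose, 9 fell and 22 were not called (21 adjusted over the list alone, 9 higher and 12 lower), and its median log2 change was -0.06 while its mean was 0.17 and camera pointed up (adjusted p = 0.514, and adjusted p = 0.834 with an estimated correlation). Among those that fell were the repressor genes JAZ8 (log2 change -0.73, adjusted p = 0.000308), JAZ3 (-0.60) and JAZ4 (-0.53), and the biosynthesis gene LOX1.1 (-0.98). Controls of labelling differed between the groups as given above.

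RTS (LOC4326940), expressed in the tapetum, rose at least 10.1-fold (from 4.31 ± 0.18 to 7.99 ± 0.05, adjusted p = 6.01e-07), OsC6 (LOC4350790) had an adjusted p of 4.13e-06, and OsRAFTIN1 (LOC4345929), a BURP-domain protein of the tapetum, rose 2.53-fold. Of the 5 measured pollen and late anther genes, 3 rose, 0 fell and 2 were not called (4 adjusted over the list alone, all higher; camera adjusted p = 0.00129, and adjusted p = 0.374 with an estimated correlation). OsC4 had a log2 change of 1.60, which is also the list's median, with an adjusted p of 0.12 and a wild-type SD of 1.46. Its change was 0.78 (adjusted p = 0.048) without wild type replicate 1 and 2.19 (adjusted p = 0.0366) without wild type replicate 2. Of 13 measured anther, tapetum and early germ cell genes, 1 rose (OsC6), 1 fell (BHLH142, log2 change -1.07, adjusted p = 0.0104, and 0.105 in an unmoderated linear model) and 11 were not called (2 adjusted over the list alone). That list had a median log2 change of -0.08 but a mean of 0.14, and camera pointed up (adjusted p = 0.837, and adjusted p = 0.898 with an estimated correlation). MSP1, which limits the number of sporogenous cells, had a log2 change of -0.18 (adjusted p = 0.0944) and GAMYB -0.20 (adjusted p = 0.128).

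Of 21 measured floral organ identity genes, 5 rose, 0 fell and 16 were not called (8 adjusted over the list alone, all higher). The stamen and carpel gene OsMADS58 (LOC4338067) rose by 0.49 (SE 0.11, adjusted p = 0.0233) on the log2 scale, the B-class genes OsMADS16 (LOC4342047), OsMADS4 (LOC4338842) and OsMADS2 (LOC4325001) by 0.39, 0.27 and 0.22, and OsMADS34 (LOC4334141), which acts in inflorescence and spikelet development, by 0.27. With 1 array fewer these calls were often lost at changes of similar size. OsMADS2 missed the threshold whichever array was left out (log2 changes of 0.21 to 0.25, adjusted p between 0.0556 and 0.11), OsMADS34 whichever array other than wild type replicate 1 was left out (0.24 to 0.29, adjusted p up to 0.0821), OsMADS4 and OsMADS16 whichever array other than wild type replicate 2 was left out (0.23 to 0.28 and 0.31 to 0.42, adjusted p up to 0.084 and 0.0845), and OsMADS58 without wild type replicate 3 (0.53, adjusted p = 0.0544) or sro replicates 2 (0.45, adjusted p = 0.0751) or 3 (0.47, adjusted p = 0.0803). OsMADS58 (adjusted p = 0.128), OsMADS16 (0.116) and OsMADS4 (0.0532) also missed it in an unmoderated linear model, at the same changes. The carpel gene DL (LOC4332058) had a log2 change of -0.33 (SE 0.12, adjusted p = 0.117), and passed the test without sro replicate 1 (-0.47, adjusted p = 0.0294). The C-class gene OsMADS3 (LOC9271572) had a log2 change of 0.14 (adjusted p = 0.469). The ovule gene OsMADS13 (LOC4351753) averaged 4.74 ± 0.32 in wild type and, below the fungal probe sets, 4.51 ± 0.09 in sro (adjusted p = 0.335). As a list they were shifted up against other genes (mean shift 0.18, camera adjusted p = 0.0131), with adjusted p = 0.748 with an estimated correlation. Without wild type replicate 1 the shift was 0.15 (adjusted p = 0.0551).

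**Figure D1:**
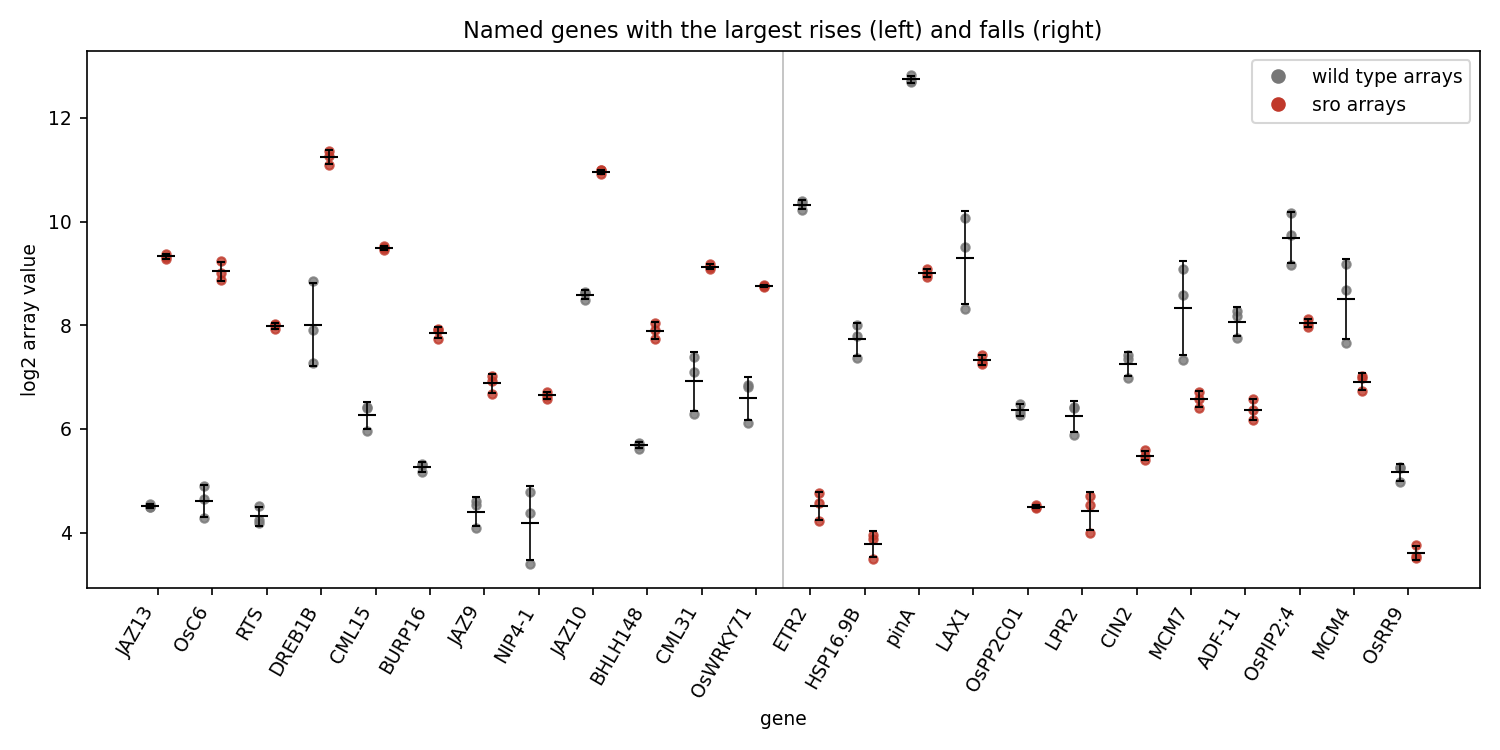
Log2 array values of the 24 named genes with the largest rises and falls, for 3 wild-type arrays (grey) and 3 sro arrays (red), with black bars for the mean and SD. JAZ13 went from 4.52 to 9.33 and ETR2 from 10.33 to 4.51, and the wild-type arrays of DREB1B, LAX1 and MCM7 were spread more widely than their sro arrays.

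Of 30 measured DNA replication genes, 15 fell, 1 rose and 14 were not called (20 adjusted over the list alone, 19 lower and 1 higher), with a mean log2 change of -0.58 and a median of -0.42. MCM7 (LOC4352514) fell from 8.33 ± 0.90 to 6.57 ± 0.16, MCM4 (LOC107275673) from 8.51 ± 0.78 to 6.91 ± 0.16, MCM5 by 1.46 and MCM3 by 1.28 on the log2 scale. OsRPA32C, a subunit of replication protein A, rose by 0.34. The list was shifted against other genes by -0.51 (camera adjusted p = 0.037, and adjusted p = 0.805 with an estimated correlation). Without wild type replicate 1 the shift was -0.36 (adjusted p = 0.12), and without sro replicate 1 it was -0.50 (adjusted p = 0.0637). With 1 array fewer, MCM7 missed the threshold at a similar change without wild type replicate 3 (-1.63, adjusted p = 0.0754) or sro replicate 1 (-1.83, adjusted p = 0.0501), 2 (-1.77, adjusted p = 0.0514) or 3 (-1.68, adjusted p = 0.0617). So did MCM4 without wild type replicate 3 (-1.51, adjusted p = 0.0652) or sro replicate 2 (-1.50, adjusted p = 0.0518), and MCM5 without wild type replicate 3 (-1.42, adjusted p = 0.0539). In an unmoderated linear model, at the same changes, MCM7 (adjusted p = 0.142), MCM4 (0.131), MCM5 (0.118) and MCM3 (0.109) all missed it. The median of the list was -0.45, -0.35 and -0.43 in sro replicates 1, 2 and 3 taken singly, an order that the dap spike values of 10.3, 7.95 and 9.48 share. Of 40 measured cyclins and CDK regulators, 15 fell, 2 rose and 23 were not called (22 adjusted over the list alone, 19 lower and 3 higher; camera adjusted p = 0.148, and adjusted p = 0.779 with an estimated correlation). The mitotic cyclin genes CYCB2-2 and CYCB1-1 fell by 0.91 and 0.54, and the mitotic kinase gene CDKB2-1 by 0.60. Of 6 histone genes, 2 fell and 4 were not called (3 adjusted over the list alone, all lower; camera adjusted p = 0.514, and adjusted p = 0.834 with an estimated correlation). Those that fell were CenH3, the centromeric histone (-0.50), and H2B.10 (-0.57). H2B.7, which also passed over the list alone, missed the threshold over all probe sets (-0.23, adjusted p = 0.0888). It passed that threshold without wild type replicate 2 (-0.30, adjusted p = 0.0382).

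LAX1 (LOC4327431), required for axillary meristems, fell by 1.98 (SE 0.37, adjusted p = 0.0107) on the log2 scale, from 9.30 ± 0.90 in wild type to 7.32 ± 0.10 in sro, and missed the threshold in an unmoderated linear model (the same change, adjusted p = 0.111). OPB, a C2H2 zinc finger gene of leaf and flower development, fell by 0.61. Of 10 measured meristem and inflorescence regulators, 4 fell and 6 were not called (6 adjusted over the list alone, all lower; shift -0.38, camera adjusted p = 0.151, and adjusted p = 0.779 with an estimated correlation), and the list passed camera without wild type replicate 2 (shift -0.51, adjusted p = 0.0153). Of 22 YABBY, WOX and KNOX genes, 7 fell and 15 were not called (10 adjusted over the list alone, all lower), with OsYAB2 at -0.42 and OsYAB3 at -0.35 (camera adjusted p = 0.181, and adjusted p = 0.779 with an estimated correlation). Of 30 growth-regulating factor, TCP and SPL genes, 11 fell and 19 were not called (13 adjusted over the list alone, all lower; camera adjusted p = 0.122, and adjusted p = 0.748 with an estimated correlation). OsGRF1, which promotes organ growth, fell by 1.25 and the TCP genes PCF5 and PCF6 by 1.15 and 0.88. The C2H2 zinc finger list had 2 measured genes, OPB and ART1 (log2 change 0.17, adjusted p = 0.486), too few for a test of the list.

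Of 69 auxin genes, 25 fell, 6 rose and 38 were not called (35 adjusted over the list alone, 27 lower and 8 higher; camera adjusted p = 0.181, and adjusted p = 0.779 with an estimated correlation), among them the repressor genes IAA14, which fell from 5.83 ± 0.16 to the level of the fungal probe sets (4.69 ± 0.08), IAA6 (-0.96), which fell, and IAA9 (0.64), which rose. Of 33 cytokinin genes, 9 fell and 24 were not called (10 adjusted over the list alone, all lower; camera adjusted p = 0.514, and adjusted p = 0.834 with an estimated correlation). The response regulator gene OsRR9 (LOC4349747) fell at least 1.39-fold (from 5.16 ± 0.17 to 3.61 ± 0.13, adjusted p = 0.000119) and the cytokinin oxidase gene CKX4 fell by 1.01 on the log2 scale. Of 21 brassinosteroid genes, 6 fell and 15 were not called (7 adjusted over the list alone, all lower; camera adjusted p = 0.122, and adjusted p = 0.689 with an estimated correlation), with the biosynthesis genes CYP724B1 and CYP85A1 at -1.35 and -0.53. Of 13 ethylene genes, 4 fell and 9 were not called (4 adjusted over the list alone; camera adjusted p = 0.377, and adjusted p = 0.805 with an estimated correlation). ETR2 (LOC4335058) had an adjusted p of 3.26e-07, its second probe set lay below the fungal probe sets (mean level 3.33, log2 change -0.90), and the receptor gene ERS2 fell by 0.72. Of 26 abscisic acid genes, 6 rose, 2 fell and 18 were not called (13 adjusted over the list alone, 8 higher and 5 lower). EM, a late embryogenesis protein gene, rose by 0.74 and the kinase gene OsSAPK9 by 0.75. The list was shifted up by 0.13 (camera adjusted p = 0.037), with adjusted p = 0.779 with an estimated correlation. The shift was 0.075 without wild type replicate 1 (adjusted p = 0.12) and 0.12 without sro replicate 1 (adjusted p = 0.0637).

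Other named genes also had large falls. HSP16.9B (LOC4325698), a small heat shock protein gene, fell at least 8.21-fold (from 7.73 ± 0.33 to 3.77 ± 0.25), and pinA (LOC9268662) had a log2 change of -3.74 (SE 0.07). Some genes with only a locus number fell more, such as LOC4326047 on chromosome 1 (log2 change -6.38). OsPP2C01 (LOC4324414) and LPR2 fell at least 3.18-fold (from 6.36 ± 0.11 to 4.50 ± 0.03) and 2.92-fold (from 6.24 ± 0.31 to 4.42 ± 0.37). The invertase gene CIN2 (LOC4335790), ADF-11 (LOC4352848), which encodes an actin depolymerizing factor, and the aquaporin gene OsPIP2;4 (LOC4343119) had log2 changes of -1.77, -1.70 and -1.65. OsPIP2;4 missed the threshold in an unmoderated linear model (the same change, adjusted p = 0.0521). Of the named genes with a measured change of at least 4-fold, HSP16.9B, pinA and NIP4-1 lie among the first 300 measured genes of chromosome 1. OsPP2C01, LPR2, LAX1 and OPB changed less and also lie on chromosome 1, but their place along it was not examined. Of the 67 genes that changed at least 4-fold and have a chromosome, 27 lie on chromosome 1, which holds 14.8% of the 17903 placed genes. Of those 27 genes, 15 lie among the first 300 of its 2649 measured genes.

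**Figure D2:**
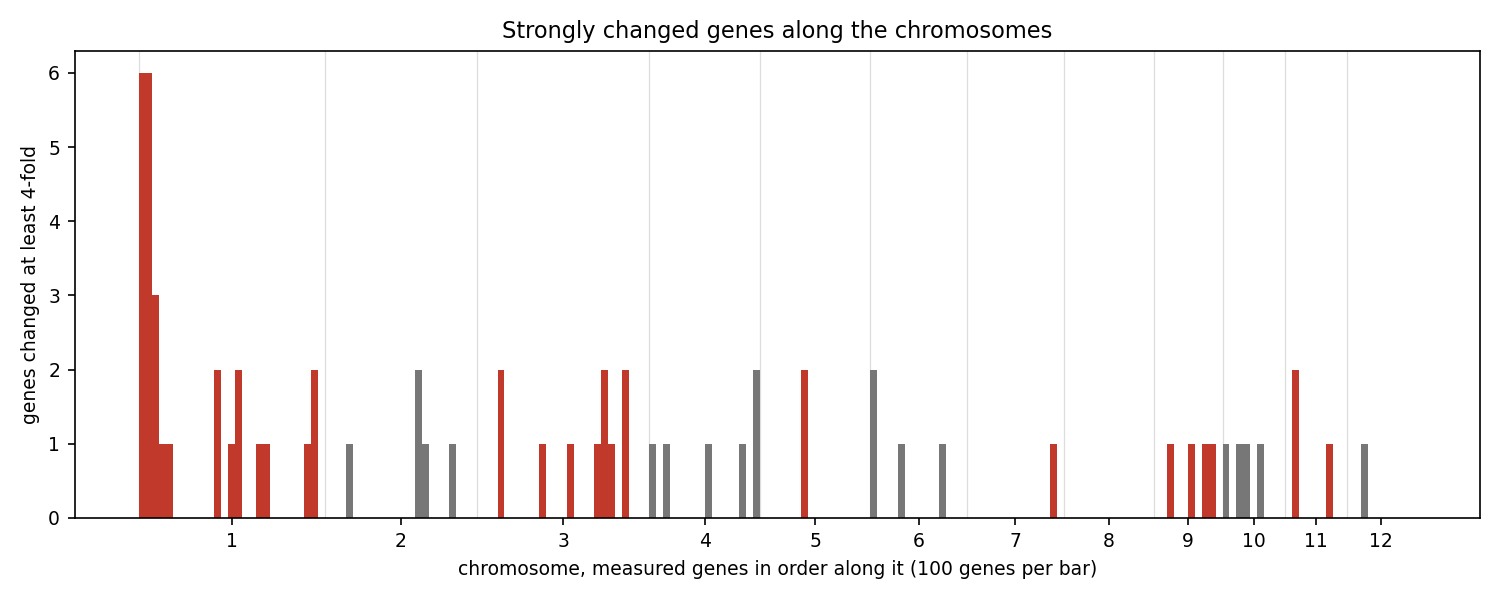
Number of genes changed at least 4-fold per 100 measured genes in order along chromosomes 1 to 12. The first 2 bars of chromosome 1 hold 6 genes each, more than any other bar, and its first 300 genes include 15.

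**Figure D3:**
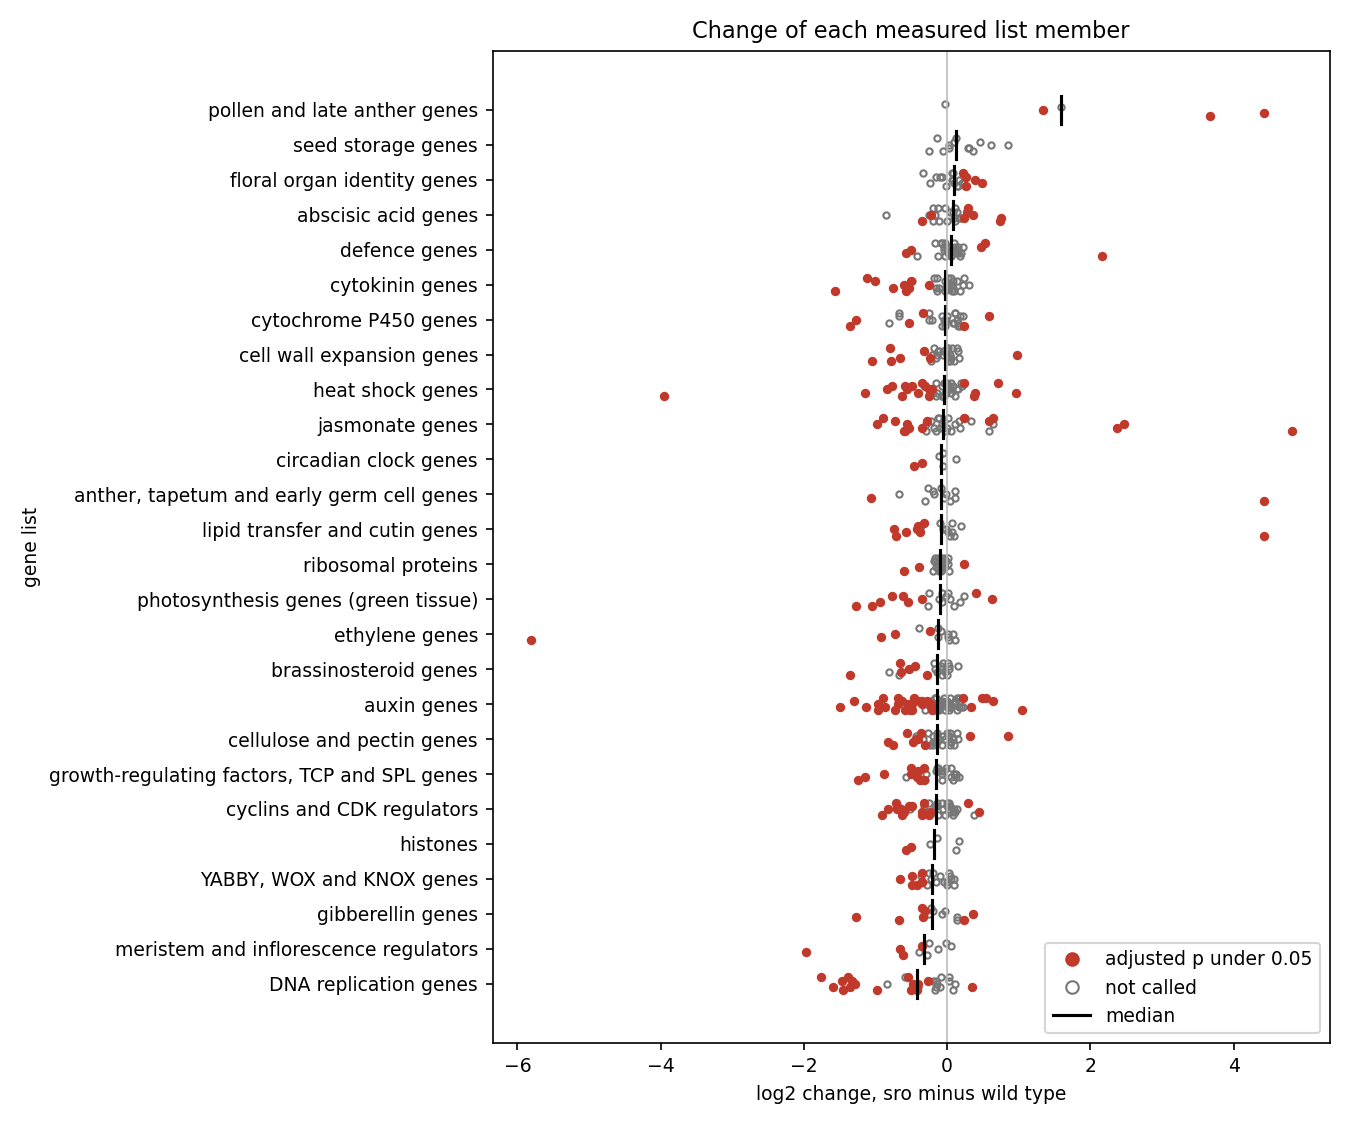
Log2 change of sro against wild type for each measured member of the 26 gene lists tested, with called genes filled, other genes open, and a black bar at each list's median. The pollen and late anther list had the highest median, 1.60, and the DNA replication list the lowest, -0.42.

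Camera called 4 of the 26 lists, 3 higher (pollen and late anther, floral organ identity, abscisic acid) and 1 lower (DNA replication), and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. Estimating the correlation from so few arrays leaves that test little power. The pollen list lost its call although its estimated correlation, -0.16, lay below the preset 0.01. A loss there does not by itself show that a list's genes vary together. By fry, which asks whether a list's genes move one way without comparing them with other genes, 24 lists passed, and 25 passed for change in either direction.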

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

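The fits with sro replicate 2 as the only sro array and those without the genes of chromosome 1 were chosen only after the results were seen. The count of 8377 changed probe sets stayed within 1.5 times under renewed quantile normalization (8387), median centring (8185), a floor (9463), only probe sets at or above the median level (9965), an intensity trend (10902), robust eBayes (8277), array weights (9329), 1 probe set per gene (6809) and without chromosome 1 (7146). The level filter and 1 probe set per gene left fewer probe sets to test (17905 in the latter). Their counts are thus larger shares of those tested. The count was 4965 in an unmoderated linear model, where the cause was not tested. It was 502 with at least 2-fold change, 668 with sro replicate 2 alone, where fewer arrays remain, and 4589 to 7907 with single arrays left out. The share of higher calls moved by less than 10 percentage points under every scaling.

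The replicate numbers do not pair the arrays. Deviations of arrays with the same number correlated at -0.019, -0.0281 and -0.00367, and 0 arrays correlated best with their own number. With the replicate block 6315 probe sets were called, of which 6049 were among the 8377, and 3 lists, the abscisic acid list missing the threshold (shift 0.13 as without it, adjusted p = 0.0586).

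Of the 24 named genes with the largest changes, 22 to 24 kept their call with single arrays left out. The count was 20 in the unmoderated model (LAX1, MCM7, OsPIP2;4 and MCM4 missed it), and 15 without chromosome 1, which holds the other 9. Genes with only a locus number, some with larger changes, are not in these counts. With sro replicate 2 alone, NIP4-1, CML31, LAX1, MCM7, OsPIP2;4 and MCM4 missed the threshold at log2 changes of 2.39, 2.20, -1.87, -1.75, -1.56 and -1.78. There the spread comes from the wild-type arrays only, so a missed threshold does not bear on the stability of these genes. The 4 called lists became 0 with an estimated correlation and 1 to 6 with single arrays left out (1 without wild type replicate 1, 2 without sro replicate 1). The DNA replication list, shifted by -0.51 with all genes, missed the threshold at about the same shift over probe sets at or above the median level (-0.50, adjusted p = 0.102) and without chromosome 1 (-0.48, adjusted p = 0.0773). With values floored, 9 rather than 15 DNA replication genes were called lower, at the same list median of -0.42. The mean correlation between arrays of different genotype, 0.993, was 0.982 over probe sets at or above the median level, and the cause was not tested.

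Over all named genes, 1892 of 2070 values under an alternative kept direction and side of the threshold, 155 lost the call and 22 gained it (in the unmoderated model, EXLA2 and RPS10-1 lost it at adjusted p = 0.079 and 0.0501; with the replicate block, OsMADS2, OsMADS34 and OsMADS4 at 0.0968, 0.0584 and 0.0633), and 1 turned, ART1, whose log2 change was -0.0125 without wild type replicate 2 and at most 0.29 without wild type replicate 1 (not called in either). Of 389 values of single lists, 370 stayed, 15 lost and 3 gained the call, and 1 turned, the clock list with the mean of all probe sets of a gene (shift 0.0537, not called). Detection calls were not used here, so what dim probe sets limit was judged by the level filter, the floor and the fungal probe sets.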

Other observations

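The tests on a chromosome segment of another origin, on labelling controls, on the stage of the inflorescences, on variation among wild-type arrays and on splits for the count of probe sets were chosen only after the result was seen. Of 45 heat shock genes, 14 fell, 5 rose and 26 were not called (21 adjusted over the list alone, 15 lower and 6 higher; camera adjusted p = 0.982, and adjusted p = 0.99 with an estimated correlation), with the chaperone gene CLPB1 at -0.56 and the heat stress factor gene HSFC1B at 0.96. Of 20 photosynthesis genes, 7 fell, 2 rose and 11 were not called (11 adjusted over the list alone, 9 lower and 2 higher; camera adjusted p = 0.514, and adjusted p = 0.834 with an estimated correlation), with CAB2R, a chlorophyll-binding protein gene, at -1.27 and OEE3 at 0.62. Of 14 gibberellin genes, 5 fell, 2 rose and 7 were not called (9 adjusted over the list alone, 7 lower and 2 higher; camera adjusted p = 0.562, and adjusted p = 0.834 with an estimated correlation), with CYP88A5 at -1.27 and OsKS1 at 0.36. Of 30 cell wall expansion genes, 6 fell, 1 rose and 23 were not called (7 adjusted over the list alone; camera adjusted p = 0.844, and adjusted p = 0.867 with an estimated correlation), with the expansin gene EXPB7 at -1.06 and EXLA2 at 0.97. Of 35 cellulose and pectin genes, 8 fell, 2 rose and 25 were not called (15 adjusted over the list alone, 13 lower and 2 higher; camera adjusted p = 0.479, and adjusted p = 0.779 with an estimated correlation), with OsCel9E at -0.76 and CSLA9 at 0.32.

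Of 18 lipid transfer and cutin genes, 7 fell, 1 rose (OsC6) and 10 were not called (8 adjusted over the list alone), and the median log2 change was -0.08 and camera pointed down (adjusted p = 0.805, and adjusted p = 0.834 with an estimated correlation) while the mean was 0.05. Of 29 cytochrome P450 genes, 4 fell, 2 rose and 23 were not called (8 adjusted over the list alone), and the mean was -0.15 and the median -0.03 (0.0066 after renewed quantile normalization and 0.023 with a floor) while camera pointed up (adjusted p = 0.514, and adjusted p = 0.779 with an estimated correlation). Of 34 defence genes, 3 rose, 2 fell and 29 were not called (5 adjusted over the list alone; shift 0.16, camera adjusted p = 0.0858, and adjusted p = 0.658 with an estimated correlation; without sro replicate 3 shift 0.17, adjusted p = 0.0361), with the chitinase gene Cht4 at -0.58. Of 25 ribosomal protein genes, 1 rose, 2 fell and 22 were not called (3 adjusted over the list alone; camera adjusted p = 0.206, and adjusted p = 0.779 with an estimated correlation), with RPS10-1 at -0.60. Of 6 clock genes, LHY (-0.47) and PRR73 (-0.35) fell and 4 were not called (2 adjusted over the list alone; camera adjusted p = 0.514, and adjusted p = 0.834 with an estimated correlation), and with 1 array fewer PRR73 missed the threshold without wild type replicate 3 (-0.33, adjusted p = 0.0515) or sro replicate 3 (-0.36, adjusted p = 0.0552), and in an unmoderated linear model (the same change, adjusted p = 0.0597). Limma called 0 of 13 seed storage genes, with 0 adjusted over the list alone and 5 at an unadjusted p under 0.05 (shift 0.29, camera adjusted p = 0.149, and adjusted p = 0.779 with an estimated correlation; fry adjusted p = 0.473). Without wild type replicate 2 the list passed camera (shift 0.41, adjusted p = 0.0153), and limma called OsTIP3;1 (log2 change 0.68, adjusted p = 0.0176) and GLUB-5 (adjusted p = 0.0116), whose wild-type mean lay below the fungal probe sets, both higher. The 10 probe sets for the blast fungus Magnaporthe averaged 4.65 in wild type and 4.69 in sro on the log2 scale (two-sided exact permutation p = 1, n = 3).

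Genes changed at least 4-fold were crowded on chromosome 1, with 27 there where 9.91 of the 67 would fall by its share of genes. The fullest chromosome held 16 at the 95th percentile of 10000 shuffles (permutation p = 1e-04, the smallest they can give), and 15 of the 27 lay among the first 300 genes (permutation p = 1e-04, likewise the smallest), where 45.3% of genes were called against 31.2% on the rest of the chromosome and 28.1% elsewhere. A candidate explanation is a chromosome segment of another origin in the sro line, which predicts an excess and a window of this kind. Probe sequences that differ between the lines may also lower or raise single probe sets there. Of 6 other probe sets of these genes, 33.3% were called in the same direction (exact 95% interval 4.33% to 77.7%), under the 50% set for that explanation but too few to separate it from a change in expression, so both stay open, as does an effect of the sro mutation itself, which was not tested.

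The rises of JAZ13, JAZ9, JAZ10, DREB1B, CML15 and CML31 were set against harvest at another time of day and against labelling or RNA quality. The 6 clock genes had a median absolute log2 change of 0.12, under the bound of 0.3, and 0 of them were called with a change of 1.5-fold or more, which argues against a large difference in time of day. The 6 genes of the jasmonate list that were called higher had medians of 1.42, 1.55 and 1.5 in sro replicates 1, 2 and 3 taken singly and 1.51 with all. Their order was the reverse of that of the 5 prime dap values (10.3, 7.95 and 9.48), the rise being smallest where dap was highest. The median with replicate 2 kept the 80% set against labelling. But each single median rests on 1 sro array and on genes picked by their call over all 3, so these values exclude nothing. A difference in labelling or RNA quality shared by the sro arrays stays open, since actin's 3 prime minus 5 prime difference was 4.94 even in sro replicate 2 and 5.13 to 5.24 in wild type, a verdict moved from excluded to undecided after the result was seen. Each of JAZ13, JAZ9, JAZ10, DREB1B, CML15 and CML31 was higher, and so nearer to sro, in wild type replicate 2 than in replicate 1. The difference was large for DREB1B (8.86 against 7.28) and small for JAZ13 (4.56 against 4.49). Variation of the kind seen among wild-type arrays, handling at harvest and the sro mutation itself were not tested for these genes and remain open.

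The fall of DNA replication genes might reflect fewer dividing cells, since 5 of 5 B-type cyclin and CDK genes also fell, with a median log2 change of -0.63 against -0.42 for the replication genes. For a later stage of the sro inflorescences, 3 of 17 anther and pollen genes rose and 1 fell (17.6% higher, exact 95% interval 3.80% to 43.4%), below the 50% set for that explanation and also under the 25% set against it, and it is left open only because the 3 are among the 5 late anther genes, a reason chosen after the result was seen. Variation in stage or harvest that also occurs among wild-type plants may contribute, because 27 of the 30 replication genes were lower in wild type replicate 2 than in replicate 1. Their median difference was -0.30, against -0.47 between sro and wild type replicate 3. Over 17905 genes these 2 differences correlated at 0.14. Labelling stays open as a part of the fall. The median was -0.35 with sro replicate 2 alone, 84.7% of the value with all sro arrays and so above the 80% set against it. But the fall was larger in sro replicates 1 and 3, where the 5 prime end of the dap spike was higher. The sro mutation itself was not tested.

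Of the 10 splits of the 6 arrays into groups of 3, the real one alone (1) called 8377 probe sets, and the highest of the others called 0. For gene lists, 3 of the 10 splits called as many as the 4 of the real one, and the highest other called 5. Every other split mixes the genotypes in both groups, so the difference between genotypes enters its spread and lowers its count of probe sets. The contrast in that count therefore says nothing about chance. With 10 splits no share under 0.05 can be reached.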
